A study of Mus musculus with 9 samples.

How the data were processed

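Total RNA of mouse embryonic orofacial tissue, the tissue that forms the face and palate, was hybridized to 9 one-colour oligonucleotide arrays. Gestation days (GD) 12, 13 and 14 had 3 arrays each, numbered as replicates 1 to 3 in the sample titles. The values are the deposited intensity of each probe set on each array, a linear value that the authors had scaled between arrays. The mean without the lowest and highest 2% of probe sets was 150.1 on every array. The labels do not give the software that turned scanned images into intensities. They do not say whether the replicates of a day came from separate litters or pools, so every p-value here measures only the spread between these samples.

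The table held 12488 probe sets, of which 66 were control probe sets of the array maker. Among the other 12422, the array annotation gave 1 gene symbol for 10833, several for 396 and none for 1193. Gene IDs of 10817 single-symbol probe sets were found in the GRCm38.p6 gene table, which was used for names only and changed 0 symbols. The single-symbol probe sets stood for 8251 genes. The table held 2 values equal to 0, 0 negative values and 0 missing values, and 0 pairs of arrays were identical. Array medians lay between 47.15 and 56.95, a ratio of 1.208, so the deposited scaling was kept. Arrays carry no read depth, and their number, 3 per day, limits the precision.

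Intensities were transformed to log2 after adding 3, the 10th percentile of all values. Control probe sets were left out, as were probe sets whose mean log2 value was at or under the 25th percentile, which corresponds to an intensity of 10.4. The remaining 9326 probe sets were tested with limma 3.58.1 in R 4.3.3. All 9 arrays entered a model of 3 group means with moderated statistics (6 residual and 2.85 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method. An adjusted p under 0.05 counted as changed. The comparisons were GD13 with GD12, GD14 with GD13, GD14 with GD12, a moderated F-test over the 3 days, and the second daily step minus the first. Fold changes derive from log2 differences with the added 3, and their standard errors (SE) come from the model. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the annotation and the plots.

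Gene lists numbered 31, each written from textbook knowledge. They covered contractile muscle and myogenic regulators; cartilage, bone, interstitial matrix, basement membrane and matrix proteases; oral epithelium with periderm; TGF-beta and BMP, FGF, WNT, hedgehog and retinoid signalling; craniofacial transcription factors and cleft palate genes; cell cycle genes and their inhibitors; embryonic globins and erythroid genes. Markers of other cells that the samples could hold covered neurons, glia, melanocytes, endothelium, leukocytes, lens and eye, liver and yolk sac. The remaining lists were glycolysis with hypoxia response, the IGF axis with imprinted growth genes, immediate early and heat shock genes, ribosomal proteins and the mitochondrial respiratory chain. Each gene was represented by its brightest tested probe set, giving 6868 genes. Lists were compared with all other genes by camera of limma, with a preset inter-gene correlation of 0.01 and adjustment over 93 tests (31 lists and 3 comparisons). The 31 list tests of the step difference were adjusted separately. Lists overlap, so their results are not independent.

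Named genes followed a rule: per comparison up to 12 rises and 12 falls of largest size among single-symbol probe sets that passed and whose 3 values in each group did not overlap. For each list up to 4 passing members with the smallest adjusted p were named, or up to 2 of the brightest where none passed. Genes reported whatever their values included Tgfb1, Tgfb2, Tgfb3, Msx1, Pax9, Osr2, Shh and the 3 embryonic globins. Osr2 had no single-symbol probe set here. The tests, filters, lists, naming rule and the alternatives listed first below were fixed before the data were examined.

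The replicate numbers were checked for pairing on the residuals of the day means. Arrays that shared a number had residual correlations of 0.19 to 0.42, and arrays with different numbers had correlations of -0.29 to -0.02. Centring on the day means ties both ranges together, so the negative one is not separate evidence. Arrays of the same number thus shared some variation across days, which the p-values of a fit without a block leave out of account. The fit without a block, as fixed, was kept as the reported one, and the value with the number as a block stands beside each named result whose call it changed. Alternatives were quantile normalization, median scaling, added values of 1 and 11, no filter, a filter at the median, limma with a trend and robust variances, array weights, the replicate block, omission of each array, only the groups compared, an estimated inter-gene correlation, fry, which tests a list against no change and not against other genes, the mean of a gene's probe sets, and the values of its other probe sets. Chosen after the data were seen were the omission of the third array of every day, the block with an estimated correlation, and the actin signal ratio as a covariate.

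The procedure was tested on simulated data of the same size, with 9326 probe sets, 200 of them changed, in 3 runs per comparison. For GD14 against GD12 it found 42.4% of log2 changes of 1, 83.3% of changes of 2 and 92.7% of changes of 3, with 5.82% of calls false. For GD13 against GD12 these shares were 48.6%, 83.2% and 91.8%, with 4.94% false. For GD14 against GD13 they were 45%, 80.4% and 96.7%, with 5.56% false. A list shifted by 0.5 among 6868 genes was called in 3 of 3 runs of each comparison, with 0 calls of other lists. The simulated probe sets varied independently of each other, and arrays of the same number shared nothing. These shares of false calls therefore do not cover correlated genes or arrays that share a number.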

Results

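The series followed gene expression in mouse embryonic orofacial tissue over 3 successive days of gestation, and the comparisons ask which genes differ between these days. Each day had 3 arrays, and each array gave 1 intensity per probe set. Median intensity of the arrays lay between 47.15 and 56.95. Correlations between arrays of a day lay between 0.951 and 0.969 across probe sets, which are not independent replicates. The ratio of the 3' to the 5' actin control signal, a measure of RNA and labelling quality, averaged 1.58 ± 0.176 (SD, n = 3) on GD12, 1.86 ± 0.529 (SD, n = 3) on GD13 and 2.04 ± 0.582 (SD, n = 3) on GD14. The third array of each day had the lowest ratio of its day, at 1.42 on GD12 and 1.37 on GD14. The third array of GD13 had the lowest ratio of all arrays. On the other arrays it was 1.54 and 1.77 on GD12, 2.09 and 2.23 on GD13, and 2.45 and 2.29 on GD14. There the ratio rose with the day without overlap. On these arrays RNA or labelling quality cannot be told apart from gestation day. The Gapdh ratio of the third arrays was 0.833, 0.802 and 0.851, against 1.09 to 1.29 on the other arrays.

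Between GD12 and GD14 the orofacial tissue gained transcripts of mineralizing bone, collagen matrix, oral epithelium and contractile muscle, and lost embryonic globin transcripts. The calls of the bone and contractile muscle lists did not hold with an estimated correlation (adjusted p = 0.0761 each). Ibsp, which encodes bone sialoprotein, rose 52.5-fold, from an intensity of 40.4 ± 12.4 to 2270 ± 619 (SD, n = 3 each), while a dimmer probe set of Ibsp had a log2 change of 1.23 (adjusted p = 0.0126). Aldh1a1, a retinaldehyde dehydrogenase, rose 13.5-fold, from 12.4 ± 1.40 to 206 ± 21.9 (SD, n = 3 each). Krt6a, an epithelial keratin, rose 8.52-fold, from 99.2 ± 15.9 to 862 ± 83.2 (SD, n = 3 each). The embryonic globin Hba-x fell 9.27-fold, from 4110 ± 637 to 440 ± 47.2 (SD, n = 3 each). In limma, 401 of 9326 probe sets changed, 302 of them higher and 99 lower on GD14, and 271 changed at least 2-fold. The 3 values of each day did not overlap for any of the 401, where such separation was seen in 22.3% of all tested probe sets and chance gives 10%. The 401 were selected on the same values, so their separation adds no support to the calls. The count was 223 without GD12 replicate 1, 262 without GD12 replicate 2, 178 without GD14 replicate 1 and 215 without GD14 replicate 2. It was 620 with the replicate number as a block, which kept 387 of the 401, and 615 with array weights. With the actin ratio as a covariate, tried after the data were seen, it was 425, which kept 331 of the 401.

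**Figure D1:**
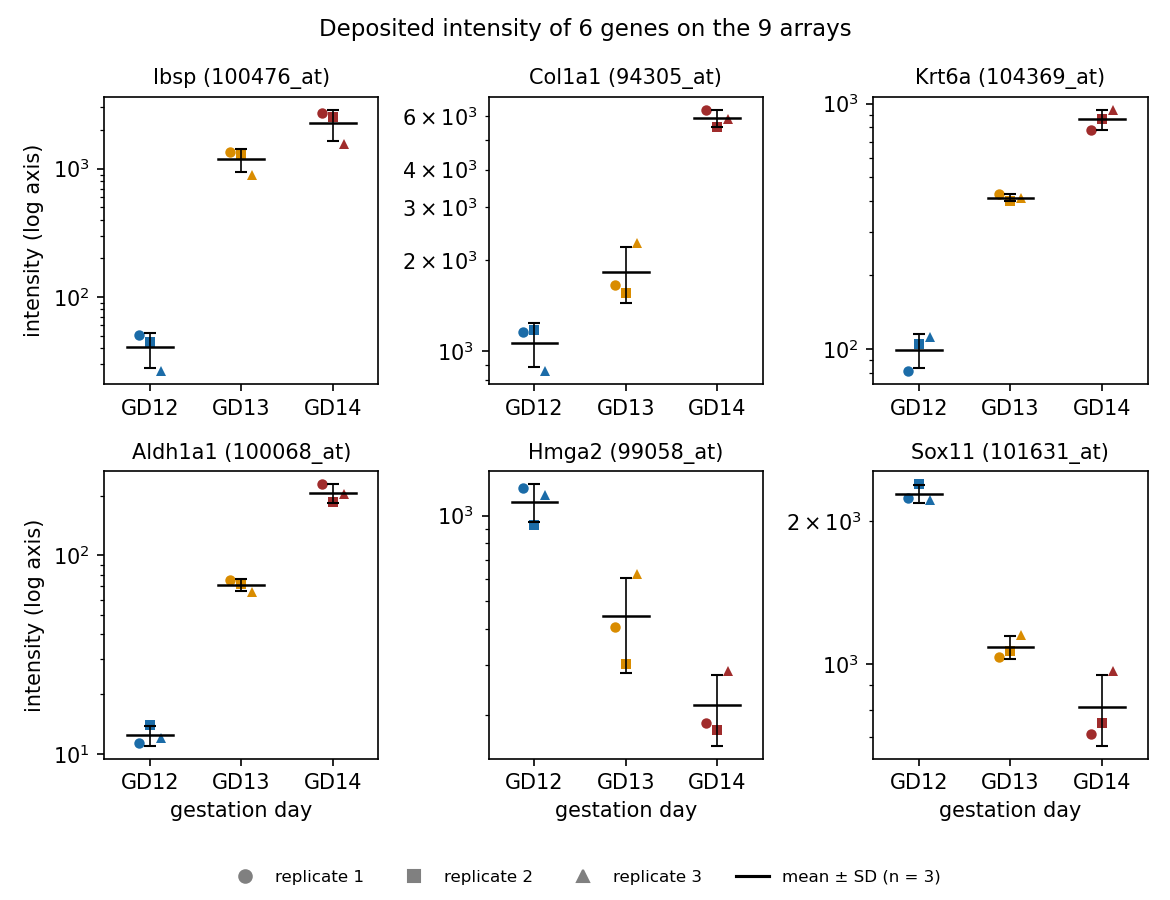
Deposited intensity (log axis, a separate range in each panel) of Ibsp, Col1a1, Krt6a, Aldh1a1, Hmga2 and Sox11 on GD12, GD13 and GD14. Points are single arrays, marked by replicate number, and bars are the mean ± SD of 3 arrays. Ibsp averaged 40.4, 1180 and 2270 on the 3 days, and Sox11 averaged 2280, 1080 and 810.

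Other rises of large size from GD12 to GD14 included genes whose GD12 mean lay under the filter intensity of 10.4, so that the size of their fold depended on the added value and is not given. These were Dmp1, a protein of mineralized matrix (3.43 ± 2.25 to 111 ± 39.7), the collagenase Mmp13 (to 103 ± 36.2), Nupr1, a stress-responsive nuclear protein (9.87 ± 13.3 to 93.9 ± 27.5), the mast cell protease Cma1 (4.23 ± 2.84 to 59.5 ± 1.02) and the collagen-binding proteoglycan Fmod (6.60 ± 1.01 to 84.8 ± 17.5; SD, n = 3 each). Some GD12 arrays also lay at or under it for the secreted protein C1qtnf3 (12.9 ± 8.89 to 188 ± 72.1), the water channel Aqp1 (13.7 ± 9.65 to 136 ± 29.2), the carbonic anhydrase Car3 (17.8 ± 20.6 to 132 ± 21.4) and the keratin Krt19, which rose to 180 ± 11.5 (SD, n = 3 each). Omission of single GD12 arrays moved the log2 change of Car3 from 3.23 to 4.05 (without replicate 2) or 2.46 (without replicate 3), of Aqp1 from 3.27 to 2.65 and of Nupr1 from 3.37 to 4.19 (both without replicate 3). Calls of Nupr1 and Car3 ended without single arrays, with the highest adjusted p at 0.086 for Nupr1 without GD14 replicate 1 and 0.0838 for Car3 without GD14 replicate 2. For Aldh1a1, a dimmer probe set had a log2 change of -0.17 (adjusted p = 0.865), so its rise rests on 1 probe set. The same holds for Aqp1, where another probe set had 0.80 (adjusted p = 0.644). Further probe sets of Cma1 (log2 -0.24 and 0.69), Fmod (0.15) and Krt19 (0.19) lay under the filter intensity and were not tested. The rises of these genes thus also rest on 1 probe set each.

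Bone genes rose as a group from GD12 to GD14. Of 10 tested members of the bone and osteoblast list, 5 rose, 0 fell and 5 did not pass; adjusted over the list alone, 7 rose and 1 fell. Alpl, the alkaline phosphatase of mineralizing tissue, went from 122 ± 14.3 to 524 ± 31.7, and the proteoglycan Ogn from 218 ± 11.6 to 814 ± 70.9 (SD, n = 3 each). The list's mean log2 change was 1.89, with camera adjusted p = 1.85e-06 and adjusted p = 0.0761 with an estimated correlation. Of 34 interstitial matrix genes, 14 rose and 0 fell, and 24 rose adjusted over the list alone. They included Dcn, the proteoglycan decorin (247 ± 35.9 to 1550 ± 104), Col1a1, a chain of type I collagen (1060 ± 177 to 5920 ± 390), and Lox, a collagen cross-linking enzyme (165 ± 27.2 to 667 ± 116; SD, n = 3 each). Another probe set of Lox did not pass (log2 0.33, adjusted p = 0.816). The matrix list's mean was 0.95, with camera adjusted p = 2.03e-14, and it held its call with an estimated correlation (adjusted p = 0.0417).

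Matrix proteases and their inhibitors had 4 rises and 0 falls among 19 genes, and 6 rises adjusted over the list alone (mean log2 0.79, camera adjusted p = 0.000313, adjusted p = 0.0888 with an estimated correlation). Ctsk, the collagen-degrading cathepsin K, went from 135 ± 8.88 to 430 ± 32.4, Mmp12, a macrophage elastase, from 22.2 ± 11.6 to 95.5 ± 24.6 (SD, n = 3 each; highest adjusted p 0.0951, without GD14 replicate 1), and Mmp9, a gelatinase, rose 7.42-fold (log2 2.89, SE 0.35). In the basement membrane list 1 of 18 genes rose, Lamb3, a laminin chain of epithelia (7.80 ± 2.38 to 76.1 ± 17.2; SD, n = 3 each), 0 fell and 2 rose adjusted over the list alone. Other probe sets did not pass for Mmp9 (log2 0.38, adjusted p = 0.632) and Lamb3 (0.42, adjusted p = 0.451). The mean of the basement membrane list was 0.44, with camera adjusted p = 0.00617 and adjusted p = 0.118 with an estimated correlation. Cartilage genes did not pass as a list (mean 0.56, camera adjusted p = 0.13). Among 16 cartilage genes 3 rose and 0 fell, and adjusted over the list alone 6 rose and 2 fell. The cartilage collagen gene Col11a1 rose from 296 ± 38.5 to 810 ± 135, and the growth plate signal Ihh from 26.0 ± 5.35 to 61.5 ± 2.40 (SD, n = 3 each). Without GD14 replicate 3 the cartilage list passed (adjusted p = 0.0429).

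Epithelial and muscle genes also rose between GD12 and GD14. Of 33 genes of oral epithelium and periderm, 12 rose and 0 fell, and 23 rose adjusted over the list alone. Lgals7, the epithelial galectin-7, went from 6.13 ± 1.54 to 73.8 ± 20.0, and Col17a1, a hemidesmosomal collagen, from 64.5 ± 10.9 to 207 ± 60.8 (SD, n = 3 each). The epithelial list's mean log2 change was 0.93 (camera adjusted p = 1.77e-12), and the call held with an estimated correlation (adjusted p = 0.0123). Of 33 genes of the contractile apparatus of skeletal muscle, 12 rose and 0 fell, and 17 rose adjusted over the list alone. Acta1, skeletal muscle actin, went from 81.4 ± 21.7 to 656 ± 148, and the myosin light chain Myl1 from 148 ± 17.9 to 476 ± 107 (SD, n = 3 each). Another myosin light chain, Myl4, rose from 92.3 ± 24.7 to 343 ± 79.1 (SD, n = 3 each; log2 0.06 on another probe set, adjusted p = 0.921), and the troponin Tnnt3 rose by a log2 of 1.77. The muscle list's mean was 0.92, with camera adjusted p = 1.52e-10 and adjusted p = 0.0761 with an estimated correlation. In the list of myogenic regulators, 1 of 13 genes rose and 0 fell, and 1 rose and 1 fell adjusted over the list alone (mean 0.11, camera adjusted p = 0.534). The riser was the transcription factor Mef2c (28.4 ± 4.58 to 75.0 ± 26.5; SD, n = 3 each), whose call ended without single arrays (highest adjusted p 0.127, without GD14 replicate 1). Its 3 other probe sets did not pass (log2 0.83, 0.20 and 1.16, adjusted p = 0.294, 0.834 and 0.504).

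**Figure D2:**
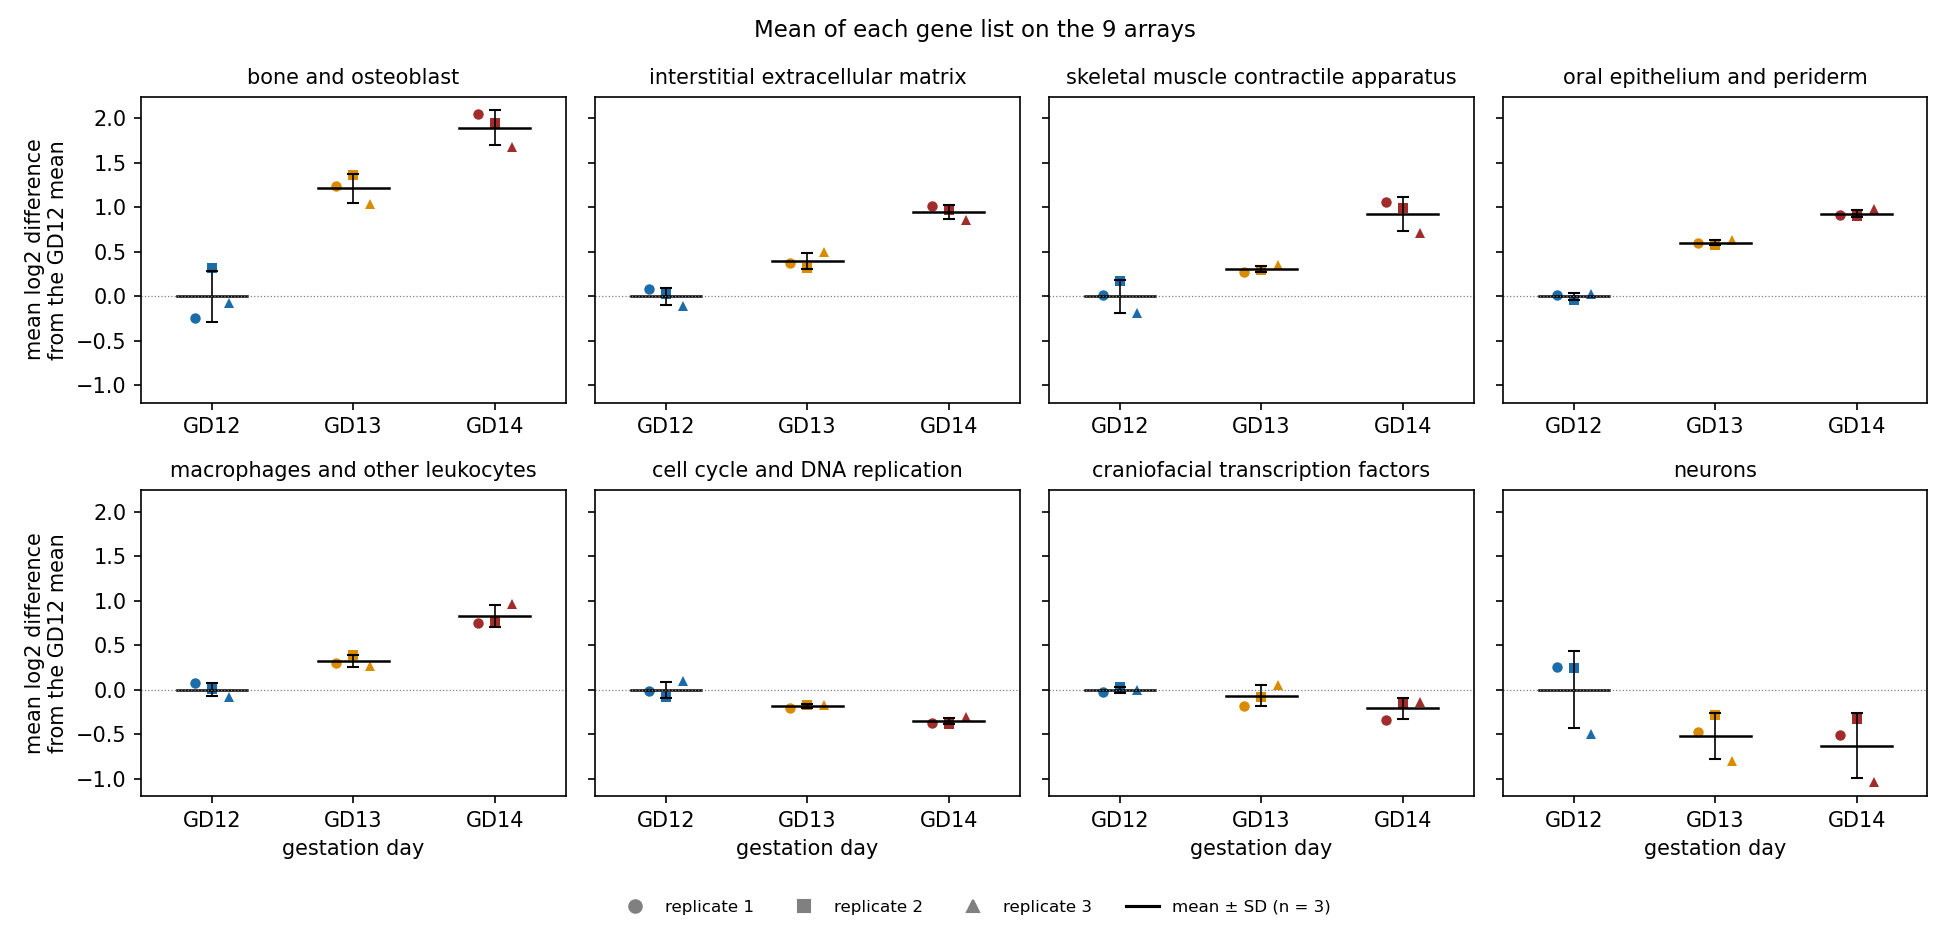
Mean log2 difference from the GD12 mean of the tested genes of 8 lists on each array. Points are arrays, marked by replicate number, and bars are the mean ± SD of 3 arrays. Between GD12 and GD14 bone genes averaged a log2 change of 1.89 and cell cycle genes one of -0.35, and in the neuron panel the third array of each day lies lowest.

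All 3 embryonic globins fell from GD12 to GD14. Besides Hba-x, Hbb-bh1 fell 10.3-fold, from 341 ± 47.9 to 33.6 ± 21.2, and Hbb-y fell 3.17-fold, from 10500 ± 1640 to 3300 ± 257 (SD, n = 3 each). The dimmer probe set of Hbb-y had a log2 change of -2.98 (adjusted p = 0.000106), against -1.67 for this one. The list had 3 falls adjusted over the list alone and a mean log2 change of -2.75 (camera adjusted p = 1.84e-07, and adjusted p = 0.0357 with an estimated correlation, which kept the call). Among 20 other erythroid genes 1 rose and 1 fell, and adjusted over the list alone 2 rose and 2 fell (mean log2 -0.03, camera adjusted p = 0.683). The adult-type globin Hbb-b2 rose from 2290 ± 165 to 4380 ± 216, and Mllt3 fell from 555 ± 16.6 to 327 ± 30.9 (SD, n = 3 each). Hba-a1, an adult-type globin, had 7540 ± 1070 on GD12 and 8040 ± 1450 on GD14 (SD, n = 3 each) and did not pass. Without GD14 replicate 1 the calls of Hbb-b2 (adjusted p = 0.0508) and Mllt3 (adjusted p = 0.0762) ended.

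**Figure D3:**
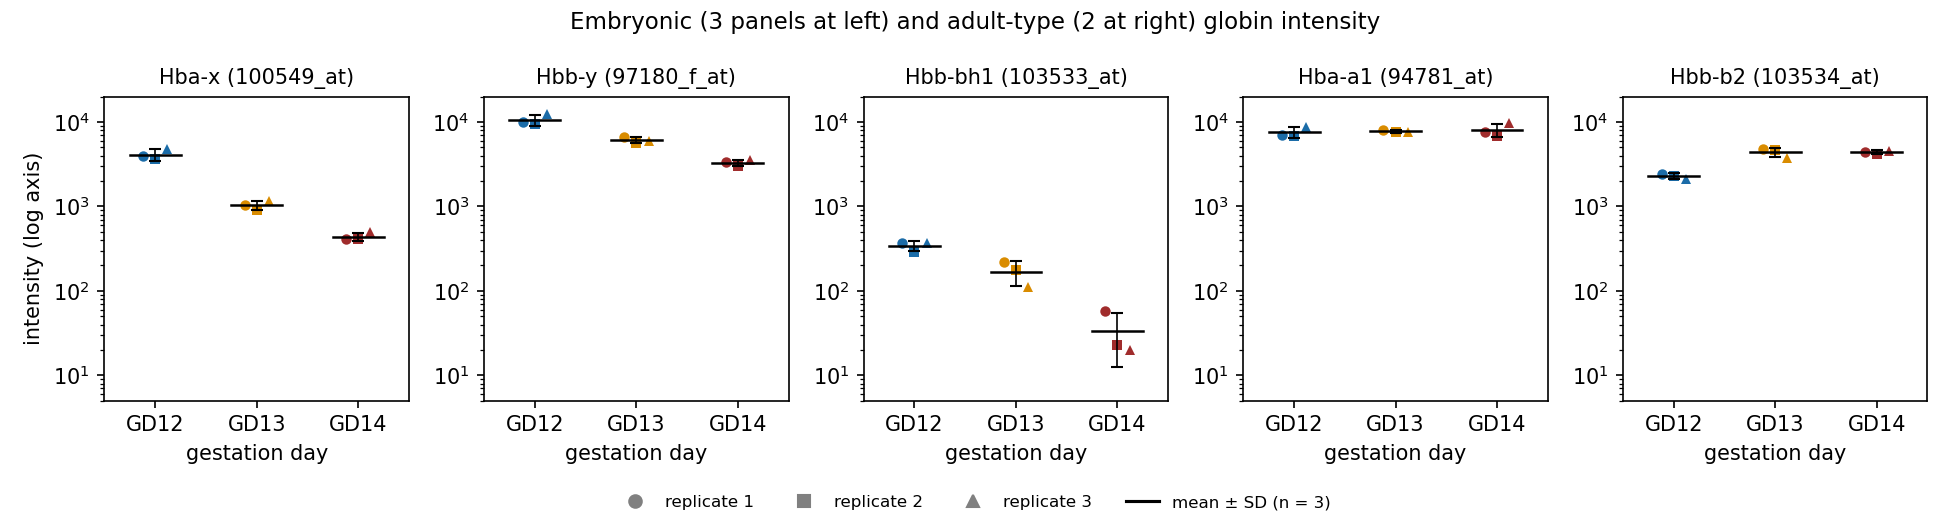
Deposited intensity (log axis, the same range in all panels) of 3 embryonic and 2 adult-type globin probe sets on GD12, GD13 and GD14. Points are arrays, marked by replicate number, and bars are the mean ± SD of 3 arrays. Hba-x averaged 4110, 1040 and 440 on the 3 days, while Hba-a1 averaged 7540, 7710 and 8040.

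Further falls between GD12 and GD14 included Hmga2, a chromatin protein of embryonic cells, which fell 5.19-fold, from 1120 ± 171 to 216 ± 60.1 (SD, n = 3 each). Nnat, an imprinted neural proteolipid, fell 3.45-fold (log2 -1.79, SE 0.25). The neural genes Mapt (tau, 3.39-fold), Napb (28.8 ± 9.54 to 6.13 ± 4.61; SD, n = 3 each), Ppp1r17 (56.2 ± 14.1 to 11.9 ± 11.7) and Myt1 (53.9 ± 23.6 to 13.5 ± 4.45; SD, n = 3 each) fell, as did the WNT agonist Rspo2 (2.98-fold), the carbonic anhydrase Car14 (3.05-fold) and Cdhr5 (from 35.9 ± 2.75; SD, n = 3). For Napb, Ppp1r17, Myt1 and Cdhr5 some GD14 arrays lay under the filter intensity of 10.4, so no fold is given, and without GD14 replicate 3 the log2 change of Ppp1r17 moved from -2.24 to -2.84. Other probe sets did not pass for Mapt (log2 -0.96 and -0.28, adjusted p = 0.0761 and 0.831) and Napb (-0.47, adjusted p = 0.623). With the replicate block, adjusted p was 0.0528 for Ppp1r17, 0.0621 for Myt1 and 0.0531 for Rspo2. Each of these 7 calls also ended without single arrays. Their highest adjusted p was 0.112 for Mapt without GD12 replicate 1, 0.0809 for Napb without GD14 replicate 2, 0.112 for Ppp1r17 without GD14 replicate 1, 0.149 for Myt1 without GD14 replicate 2, 0.117 for Rspo2 without GD14 replicate 1, 0.0899 for Car14 without GD12 replicate 3 and 0.136 for Cdhr5 without GD12 replicate 3. Of 27 neuronal genes 1 fell (Mapt) and 0 rose, and 5 fell adjusted over the list alone. The neuronal list's mean was -0.63, with camera adjusted p = 7.32e-05 and adjusted p = 0.307 with an estimated correlation, and fry, a test against no change, gave 0.11. Relative to the GD12 mean, its score was 0.25, 0.25 and -0.50 on the GD12 arrays, and -0.51, -0.33 and -1.04 on the GD14 arrays.

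Transcription factors of the face and proliferation genes were lower as groups on GD14 than on GD12. Of 45 craniofacial transcription factor genes 1 rose and 4 fell, and 3 rose and 9 fell adjusted over the list alone (mean log2 -0.21, camera adjusted p = 0.00417, adjusted p = 0.166 with an estimated correlation). Sox11, a factor of embryonic progenitors, fell from 2280 ± 99.1 to 810 ± 138, and Tbx3 from 51.9 ± 9.54 to 18.5 ± 4.11 (SD, n = 3 each). Msx1, needed for palate and tooth formation, fell from 1150 ± 209 to 584 ± 45.3, while Dlx3 rose from 59.1 ± 19.9 to 176 ± 15.5 (SD, n = 3 each). The Msx1 call ended without GD14 replicate 1 (adjusted p = 0.0666). Of 68 cell cycle and DNA replication genes 3 fell and 0 rose, and 11 fell adjusted over the list alone. The list's mean was -0.35 (camera adjusted p = 2.62e-10), and the call held with an estimated correlation (adjusted p = 0.0357). Stmn1, a microtubule regulator, fell from 4590 ± 228 to 2590 ± 237, and Rrm2, a ribonucleotide reductase subunit, from 539 ± 80.6 to 317 ± 36.4 (SD, n = 3 each). Kif2c, a mitotic kinesin, fell from 219 ± 21.6 to 138 ± 13.8 (SD, n = 3 each), a call that ended whichever single array was left out. Calls ended at their highest adjusted p for Stmn1 (0.0623) and Kif2c (0.155) without GD12 replicate 1 and for Rrm2 without GD14 replicate 2 (0.118). Among 20 cell cycle inhibitor genes 3 rose and 0 fell, and adjusted over the list alone 5 rose and 1 fell. Their mean was 0.39, with camera adjusted p = 0.00617 and adjusted p = 0.0761 with an estimated correlation. Cdkn1a, the inhibitor p21, rose from 63.2 ± 16.8 to 211 ± 24.4, and Gas6 from 51.1 ± 5.86 to 127 ± 10.9 (SD, n = 3 each). Gadd45b rose by a log2 of 1.29 (SE 0.30), with adjusted p = 0.162 without GD14 replicate 1.

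Signalling lists did not pass as groups between GD12 and GD14, but single members changed. Tgfb1 rose to 63.9 ± 13.4 from a GD12 mean under the filter intensity of 10.4, and Tgfb3, the isoform needed for palate fusion, rose 1.93-fold, from 317 ± 33.3 to 613 ± 42.6 (SD, n = 3 each). The TGF-beta binding protein Ltbp4 rose from 230 ± 46.8 to 588 ± 68.2 (SD, n = 3 each). Tgfb2 (82.3 ± 31.4 and 46.9 ± 8.07), Pax9 (53.8 ± 9.13 and 33.3 ± 10.2) and Shh (55.6 ± 11.6 and 43.4 ± 18.3) did not pass. The TGF-beta and BMP list had 3 rises and 0 falls among 45 genes, and 4 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.697). Its mean was 0.03 (-0.006 with median scaling), its median -0.03, and the test pointed down. Dusp6, a feedback phosphatase of FGF signalling, fell from 922 ± 82.4 to 474 ± 40.3 (SD, n = 3 each), the single change among 10 FGF genes, also adjusted over the list alone (mean -0.04, median 0.22, camera adjusted p = 0.807). The WNT antagonists Dkk1 (39.6 ± 6.19 to 114 ± 25.5) and Dkk2 (32.7 ± 6.14 to 60.8 ± 12.0) rose among 40 WNT genes, where 3 rose and 1 fell adjusted over the list alone (mean -0.00, camera adjusted p = 0.56). The adjusted p of Dkk2 was 0.0555 with the replicate block and 0.148 without GD12 replicate 1. In the hedgehog list Ihh rose among 13 genes, also adjusted over the list alone (mean -0.14, camera adjusted p = 0.5).

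Retinoid genes changed in both directions between GD12 and GD14. Among 15 members 3 rose and 1 fell, and 3 rose and 2 fell adjusted over the list alone (mean 0.35, camera adjusted p = 0.681), while fry, a test against no change, gave an adjusted p of 0.00528. Besides Aldh1a1, the retinol carrier Rbp4 rose from 17.9 ± 10.6 to 88.1 ± 10.9 and Aldh1a7 from 19.6 ± 8.77 to 62.4 ± 12.3, while the retinaldehyde dehydrogenase Aldh1a2 fell from 125 ± 11.1 to 64.2 ± 5.84 (SD, n = 3 each). Calls ended without GD14 replicate 2 for Rbp4 (adjusted p = 0.0676), without GD14 replicate 1 for Aldh1a7 (0.0757) and without GD12 replicate 1 for Aldh1a2 (0.0524). Of 38 genes whose loss causes cleft palate in mice 3 rose and 2 fell, and 4 rose and 3 fell adjusted over the list alone. Their mean was -0.16, with camera adjusted p = 0.0382 and adjusted p = 0.252 with an estimated correlation. The risers were Tgfb3, Col11a1 and Col11a2 (whose call ended without GD14 replicate 1, adjusted p = 0.0593), and Msx1 was among those that fell. Without GD14 replicate 2 the adjusted p of this list was 0.0975, the highest of 4 single arrays that ended its call; the others were GD12 replicates 1 (0.0696) and 2 (0.058) and GD14 replicate 1 (0.0641). It was 0.0744 with a filter at the median, 0.0517 with a trend and robust variances and 0.0503 with the mean of a gene's probe sets. A test against no change, fry, gave 0.0848.

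Leukocyte genes rose between GD12 and GD14. Of 22 macrophage and other leukocyte genes 9 rose and 0 fell, and 13 rose adjusted over the list alone (mean log2 0.83, camera adjusted p = 1.14e-08). The call held with an estimated correlation (adjusted p = 0.0179). The mannose receptor Mrc1 rose from 18.3 ± 2.45 to 68.1 ± 10.3, the protease Ctss from 77.5 ± 17.9 to 232 ± 14.9, and the complement genes C1qa from 76.8 ± 8.88 to 186 ± 16.2 and C1qb from 43.9 ± 7.62 to 113 ± 27.9 (SD, n = 3 each). For C1qb another probe set did not pass (log2 -0.003, adjusted p = 0.998). Of 20 endothelial genes 1 rose, the lymphatic receptor Lyve1 (3.47 ± 2.74 to 38.9 ± 8.35; SD, n = 3 each), and 0 fell, also adjusted over the list alone. The endothelial mean was 0.33, with camera adjusted p = 0.0196 and adjusted p = 0.0914 with an estimated correlation. Its adjusted p was 0.0613 without the third array of every day and 0.0522 without GD12 replicate 3.

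Between GD12 and GD13, genes of bone, epithelium and matrix were already higher. The calls of the bone and matrix lists did not hold with an estimated correlation (adjusted p = 0.0761 and 0.121). Ibsp rose 27.7-fold, from 40.4 ± 12.4 to 1180 ± 246 (log2 1.19 on a dimmer probe set, adjusted p = 0.0469), and Clec11a, a bone growth factor, rose 4.27-fold, from 62.4 ± 5.59 to 276 ± 22.3 (SD, n = 3 each). Aldh1a1 rose 4.81-fold (log2 2.27, SE 0.15) and Krt6a 4.11-fold (log2 2.04, SE 0.16). The chemokine Ccl9 rose from 6.40 ± 1.06 (SD, n = 3), under the filter intensity of 10.4, to a mean of 47.3. Hba-x fell 3.95-fold, from 4110 ± 637 to 1040 ± 130, and Sox11 fell 2.11-fold, from 2280 ± 99.1 to 1080 ± 60.2 (SD, n = 3 each). A dimmer probe set of Aldh1a1 (log2 0.42, adjusted p = 0.725) and another of Sox11 (-1.08, adjusted p = 0.0784) did not pass. Limma called 60 probe sets, 53 higher and 7 lower on GD13. The count was 17 without GD13 replicate 1, 27 without GD12 replicate 1, 31 without GD13 replicate 2, and 37 without either GD12 replicate 2 or GD14 replicate 1. It was 10 without the third array of every day and 201 with array weights.

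Further rises from GD12 to GD13 were Mmp9 (6.84-fold), C1qtnf3 (12.9 ± 8.89 to 86.9 ± 16.2), Cyp2f2 (11.5 ± 3.02 to 65.6 ± 5.68) and the guidance cue Sema3e (16.1 ± 10.2 to 67.9 ± 10.9; SD, n = 3 each). From GD12 means under the filter intensity of 10.4, Lgals7 rose to 49.7 ± 27.3, Cma1 to 27.3 ± 0.954 and Lamb3 to 38.3 ± 6.47 (SD, n = 3 each). Cd86, a costimulatory ligand, fell from 31.4 ± 4.42 to 9.73 ± 1.71 (SD, n = 3 each). On GD14 it stood at 25.3 ± 7.87 (SD, n = 3) and did not pass against GD12 in limma (log2 -0.32, adjusted p = 0.556). Further falls were the transcription factor Ebf3 (2.23-fold), Apbb2 (2.12-fold), Limch1 (2.04-fold) and B230308N11Rik (1.85-fold). Other probe sets did not pass for Mmp9 (log2 0.73, adjusted p = 0.469), Lamb3 (0.79, adjusted p = 0.277), Ebf3 (-0.78, adjusted p = 0.195) and Limch1 (adjusted p = 0.184). With the replicate block the adjusted p was 0.0662 for Sema3e, 0.0662 for Cd86, 0.0617 for Apbb2 and 0.0575 for Limch1. Omission of single arrays ended calls, with the highest adjusted p at 0.0518 for Mmp9 without GD12 replicate 1, 0.0522 for Cma1 and Lamb3 without GD13 replicate 1, and 0.102 for Lgals7 without GD12 replicate 2. Without GD13 replicate 2 it was 0.147 for C1qtnf3, 0.168 for Sema3e, 0.173 for Cd86, 0.144 for Ebf3, 0.206 for Apbb2 and 0.147 for B230308N11Rik. Without GD13 replicate 1 it was 0.126 for Sox11 and 0.167 for Limch1.

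As a group, epithelial genes had 3 rises and 0 falls among 33 from GD12 to GD13, and 9 rises adjusted over the list alone (mean log2 0.61, camera adjusted p = 1.54e-09), a call that held with an estimated correlation (adjusted p = 0.0144). Besides Krt6a and Lgals7, the keratin Krt17 rose from 110 ± 16.6 to 416 ± 101 (SD, n = 3 each), with adjusted p = 0.111 without GD12 replicate 1 and, on its other probe sets, 0.000402 and 0.753. Bone genes had 3 rises and 0 falls among 10, and 6 rises adjusted over the list alone (mean 1.21, camera adjusted p = 7.96e-06, adjusted p = 0.0761 with an estimated correlation). Interstitial matrix genes had 2 rises, Dcn (247 ± 35.9 to 915 ± 61.5) and Lum (761 ± 110 to 1520 ± 31.4; SD, n = 3 each), and 0 falls among 34, with 9 rises adjusted over the list alone. Their mean was 0.40, with camera adjusted p = 4.18e-06 and adjusted p = 0.121 with an estimated correlation. The call of Lum ended without GD13 replicate 2 (adjusted p = 0.141). Embryonic globins had 1 fall and 0 rises among 3, and 3 falls adjusted over the list alone (mean -1.27, camera adjusted p = 7.52e-06, adjusted p = 0.0549 with an estimated correlation). Neuronal genes had 0 rises and 0 falls among 27, and 2 falls adjusted over the list alone (mean -0.52, camera adjusted p = 3.89e-05, adjusted p = 0.297 with an estimated correlation). The brightest neuronal genes were Tubb3 (1060 ± 114 and 794 ± 53.3) and Gap43 (541 ± 206 and 400 ± 126; SD, n = 3 each).

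Cell cycle genes had 0 rises and 0 falls among 68 from GD12 to GD13, also adjusted over the list alone (mean -0.18, camera adjusted p = 7.52e-06, adjusted p = 0.0761 with an estimated correlation). Their inhibitors had 0 changes among 20 and 3 rises adjusted over the list alone (mean 0.28, camera adjusted p = 0.00866, adjusted p = 0.0761 with an estimated correlation). Contractile muscle genes had 0 changes among 33, also adjusted over the list alone (mean 0.31, camera adjusted p = 0.00414, adjusted p = 0.363 with an estimated correlation). This call ended without GD12 replicate 3 (adjusted p = 0.111) and without the third array of every day (adjusted p = 0.0734). Leukocyte genes had 0 changes among 22 and 4 rises adjusted over the list alone (mean 0.32, camera adjusted p = 0.00469, adjusted p = 0.0761 with an estimated correlation, adjusted p = 0.0613 without the third array of every day). Matrix proteases had 2 rises, Ctsk and Mmp9, and 0 falls among 19, and 3 rises adjusted over the list alone (mean 0.41, camera adjusted p = 0.0325, adjusted p = 0.29 with an estimated correlation). Their adjusted p was 0.121 without GD12 replicate 1, 0.0805 without GD12 replicate 3, 0.0536 without GD13 replicate 2 and 0.0601 without the third array of every day. Cleft palate genes had 0 changes among 38, and 3 rises and 2 falls adjusted over the list alone (mean -0.14, camera adjusted p = 0.0325, adjusted p = 0.241 with an estimated correlation). Their adjusted p was 0.0694 without GD12 replicate 1, 0.0531 without GD12 replicate 2, 0.0823 without GD13 replicate 1 and 0.0993 without GD13 replicate 2. Basement membrane genes (mean 0.07, camera adjusted p = 0.767) and endothelial genes (mean 0.06, camera adjusted p = 0.807) had a positive mean, a negative median of -0.07 and -0.01, and a test that pointed down.

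Between GD13 and GD14, collagen matrix genes rose and an embryonic globin fell. Col1a1 rose 3.27-fold, from 1830 ± 389 to 5920 ± 390, Fmod 4.10-fold, from 18.8 ± 6.60 to 84.8 ± 17.5, and Aldh1a1 2.81-fold, from 71.1 ± 5.14 to 206 ± 21.9 (SD, n = 3 each). Hbb-y fell on the dimmer of its probe sets, from 3560 ± 569 to 889 ± 163 (SD, n = 3 each), while the brighter one did not pass (adjusted p = 0.136). Hba-x did not pass either, but did with the replicate block (adjusted p = 0.0389). These 4 probe sets, 3 higher and 1 lower, were all that limma called, and 670 had an unadjusted p under 0.05, where chance gives 466. Another probe set of Col1a1 did not pass (log2 0.96, adjusted p = 0.333). With the replicate block the adjusted p was 0.0825 for Col1a1 and 0.0654 for Fmod. The count was 0 without any one of GD12 replicate 2, GD13 replicates 1 and 2, and GD14 replicates 1, 2 and 3, where 671, 532, 474, 537, 697 and 827 had an unadjusted p under 0.05. It was 26 in limma with a trend and robust variances. For Aldh1a1 the dimmer probe set had a log2 change of -0.59 (adjusted p = 0.841).

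Several groups moved together from GD13 to GD14. Interstitial matrix genes had 2 rises and 0 falls among 34, and 14 rises adjusted over the list alone (mean log2 0.55, camera adjusted p = 3.28e-16). Leukocyte genes had 0 changes among 22 and 8 rises adjusted over the list alone (mean 0.51, camera adjusted p = 3.37e-09). Embryonic globins had 0 changes among 3 by their brightest probe sets and 3 falls adjusted over the list alone (mean -1.48, camera adjusted p = 4.77e-08). Epithelial genes had 0 changes among 33 and 4 rises adjusted over the list alone (mean 0.33, camera adjusted p = 4.65e-06). Basement membrane genes had 0 changes among 18 and 3 rises adjusted over the list alone (mean 0.37, camera adjusted p = 7.67e-06). Endothelial genes had 0 changes among 20, also adjusted over the list alone (mean 0.27, camera adjusted p = 0.000102). With an estimated correlation these 6 calls held, at adjusted p of 0.0357, 0.0179, 0.0357, 0.0234, 0.0417 and 0.0357. Among the brightest members, Col4a1 of basement membranes had 612 ± 100 on GD13 and 791 ± 93.6 on GD14 (SD, n = 3 each), and the complement gene C1qc had a log2 change of 0.65 (SE 0.17).

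Contractile muscle genes had 0 changes among 33 from GD13 to GD14 and 10 rises adjusted over the list alone (mean 0.62, camera adjusted p = 4.21e-12, adjusted p = 0.0761 with an estimated correlation). Cardiac actin Actc1 had 709 ± 80.3 on GD13 and 1240 ± 275 on GD14 (SD, n = 3 each), and the slow troponin Tnni1 had a log2 change of 0.74 (SE 0.21). Bone genes had 0 changes among 10 and 4 rises adjusted over the list alone (mean 0.68, camera adjusted p = 7.52e-06, adjusted p = 0.0761 with an estimated correlation). Matrix proteases had 0 changes among 19 and 1 rise adjusted over the list alone (mean 0.38, camera adjusted p = 0.00274, adjusted p = 0.137 with an estimated correlation). Cell cycle genes had 0 changes among 68, also adjusted over the list alone (mean -0.17, camera adjusted p = 1.12e-05, adjusted p = 0.0761 with an estimated correlation). Craniofacial transcription factors had 0 changes among 45, also adjusted over the list alone (mean -0.14, camera adjusted p = 0.0211, adjusted p = 0.261 with an estimated correlation). Their adjusted p was 0.219 without GD13 replicate 3 and 0.17 without GD14 replicate 1. Mitochondrial respiratory chain genes had 0 changes among 70, also adjusted over the list alone (mean -0.10, camera adjusted p = 0.00414, adjusted p = 0.298 with an estimated correlation). Their adjusted p was 0.143 without GD13 replicate 1 and 0.0854 without GD14 replicate 2. Retinoid genes (mean 0.12, median 0.06, camera adjusted p = 0.946) and erythroid genes (mean 0.01, median 0.03, camera adjusted p = 0.807) had a positive mean and a test that pointed down.

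Over the 3 days together, most genes that changed from GD12 to GD14 moved one way in both steps. Of the 401 probe sets, 380 had both daily steps in the direction of the whole change, which is 94.8%, against 75.6% in simulated groups without any change. The first step was the larger one in 267, with a median share of 60.7% of the change, and 341 passed in neither daily step. Of the 60 probe sets called between GD12 and GD13, 57 were also called between GD12 and GD14 in the same direction, 52 rises and 5 falls. These comparisons share the GD12 arrays, so overlap arises without any shared change. Equally long lists from simulated unchanged groups shared a median of 27 and at most 35, and independent lists would share 1.72 rises and 0.0743 falls, so part of the overlap may come from the shared arrays. The limma F-test over the 3 days called 241 probe sets, with 235 of them among the 401. Its count was 88 without GD14 replicate 1, 106 without GD14 replicate 2, 113, 154 and 150 without GD12 replicates 1, 2 and 3, and 146 and 159 without GD13 replicates 1 and 2. It was 84 without the third array of every day. The limma test of whether the daily steps differed called 0 probe sets (smallest adjusted p 0.135), and 453 had an unadjusted p under 0.05, where chance gives 466.

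Of the 93 list tests 42 passed, 28 of them up and 14 down, and 12 of the calls held with an estimated correlation. With the replicate block and an estimated correlation together 0 of the 93 camera tests passed, where 41 passed with the block alone. Omission of each array in turn left 32 of the 42 calls in place throughout.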

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

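The tests on the globins, the third arrays and the neurons, and the regroupings of the step difference, were chosen only after their results had been seen.

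For 5 gene lists the second daily step differed from the first in camera, which is the test of the difference itself. The mean difference in log2 change, second step minus first, was 0.31 for contractile muscle genes (adjusted p = 0.0181), 0.3 for basement membrane genes (0.0181), 0.42 for neuronal genes (0.046), 0.22 for endothelial genes (0.0428) and -0.23 for mitochondrial respiratory chain genes (0.0181). With an estimated correlation none of these 5 passed (adjusted p = 0.516, 0.402, 0.618, 0.402 and 0.441 in that order). With the replicate block the endothelial list did not pass (adjusted p = 0.0531), and the other 4 had adjusted p of 0.00516, 0.0127, 0.00516 and 0.00516 in that order.

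The embryonic globins Hba-x, Hbb-y and Hbb-bh1 fell from GD12 to GD14. Less blood in the older tissue would lower the other red cell genes as well, but their median log2 change was -0.09 (SD over 20 genes 0.52), where Hbb-y, with the smallest change of the embryonic globins, fell by 1.67 on the log2 scale by its brightest probe set. Cross-hybridization with adult-type globin RNA, as the source of the fall, would move both kinds together, but the mean change of Hba-a1 and Hbb-b2 lay 3.26 (SE 0.19) above that of the embryonic globins. Partial cross-hybridization could still have altered the size of the fall, and no probe sequences were available to check it. A wrong day label on a single array is argued against too. Over 100 other probe sets, chosen without the array tested, 0 of 9 arrays lay nearer to the mean of another day. The test cannot detect a swap of whole days, which would leave this result unchanged. A replacement of embryonic by later red cells between these days may account for the pattern and remains a hypothesis, found and tested on the same arrays.

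The third array of each day stood apart from the other arrays in the actin and Gapdh control ratios. A mislabelled day of these arrays is argued against, since 0 of 3 of these arrays lay nearer to another day over 100 probe sets chosen on the other 6 arrays. A labelling or hybridization batch shared by the third arrays is a candidate explanation that stays open. Bacterial spike-in controls, which do not come from tissue, were highest on the third array in 18 of 21 combinations of day and probe set. Chance gives 7. The intensities were scaled between arrays, so a spike-in value is relative to the signal of the tissue RNA. Less tissue signal on the third arrays would raise it too, so the spike-ins cannot tell a batch from a difference in the tissue RNA. The 7 spike-in probe sets share the added mixture, so the combinations are not independent. The labels give no batch, and a difference in the tissue or litters of the third samples was not tested.

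The neuronal list was lower on GD14 than on GD12, a camera call that did not hold with an estimated correlation (adjusted p = 0.307). The test against no change, fry, gave an adjusted p of 0.11. Whether uneven neural content of the dissections within a day was the cause could not be decided. Within each replicate number the change was -0.76, -0.58 and -0.54, with a mean of -0.63 (SD 0.12, n = 3). This reading replaced a first one by overlap of the days, with a bound of 2 SD chosen once the values were known, and it takes arrays of the same number as comparable; without it the days overlap, since 2 of the GD14 arrays lay below the lowest GD12 array and 1 did not, and an exact sign permutation over 3 pairs cannot go below p = 0.25. Uneven neural content thus stays open as a cause. A smaller share of all neural tissue in the older samples stays open as well. Glial genes could not decide it, since they moved in both directions (median 0.08, SD over 10 genes 0.84, against a neuronal median of -0.65). A change in the neurons of the growing face, which the design's ages could give, was not tested.

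Regrouping the arrays asked whether chance could give as large a result. For each pair of days the 6 arrays form 10 splits into 3 and 3, too few for a share under 0.05; the real split alone (1 of 10) gave as many probe sets. The real count and the highest of the other splits were 60 and 1 for GD13 against GD12, 4 and 1 for GD14 against GD13, and 401 and 0 for GD14 against GD12. For the F-test over the 3 days, 1 of 100 splits drawn from 280, the real one, gave as many, the smallest share these splits allow. The real count was 241 and the highest other 90, in a split that kept the GD12 arrays together. The labels do not say whether a day's replicates came from separate litters or pools. The splits cannot exclude a chance difference between pools of single days. Among the other splits with 1 array of each replicate number per group, of which 36 exist with the real one and all were fitted, the highest was 45, and grouping by replicate number gave 16. For the gene lists 1 of 100 splits, the real one, gave as many calls as the 42 found. The highest other gave 38, again with the GD12 arrays together, and grouping by replicate number gave 7. This share, again the smallest possible, covers the whole count and no single list. The other splits gave a median of 14 list calls, so ordinary regroupings also gave many at the preset correlation, and with the replicate block and an estimated correlation 0 of the 93 tests passed. Among the 36 splits with 1 array of each number per group 1, the real one, gave as many, and the highest other was again 38. For the difference between the steps the real count was 0, which every split reaches (100 of 100), so the splits say nothing about it. The highest split there called 236 probe sets, with the GD12 arrays as the middle group, which points to the structure of the days themselves.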

How the results depend on the processing

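The omission of the third array of every day, the replicate block with an estimated correlation, and the actin covariate were tried only after the data had been seen. The filter stood at an intensity of 10.4. With no filter, where more probe sets entered the adjustment and the variance estimate, 87 of 115 named calls of genes per comparison passed. Counts of changed probe sets moved by over 1.5 times as follows, and the cause was not tested except where fewer arrays or probe sets entered. For GD13 against GD12 (60) they were 35 with no filter, 94 with a filter at the median, 115 with a trend and robust variances, 201 with array weights, 31 with only the 2 groups compared and 10 without the third arrays. For GD14 against GD13 (4) they were 2 with quantile normalization, 0 with median scaling (615 at an unadjusted limma p under 0.05), 2 with an added value of 1, 16 with an added value at the 25th percentile, 0 with no filter (790 unadjusted), 19 with a filter at the median, 26 with trend and robust variances, 11 with array weights, 2 with only the 2 groups compared and 0 without the third arrays (963 unadjusted). For GD14 against GD12 (401) they were 615 with array weights, 620 with the replicate block and 227 with only the 2 groups compared; with quantile normalization, 374 of the 401 were shared, with median scaling 321, with the actin covariate 331 and without the third arrays 194. For the F-test (241) they were 369 with trend and robust variances, 405 with array weights and 84 without the third arrays. For the step difference (0) they were 2 with a filter at the median, 2 with trend and robust variances, 1 with array weights and 1 with the replicate block. Of 42 list calls, 12 passed with an estimated correlation and 0 with the block and an estimated correlation. Omission of single arrays gave 17 to 59 for GD13 against GD12, 0 to 4 for GD14 against GD13, 178 to 394 for GD14 against GD12, 88 to 239 for the F-test, 0 to 0 for the step difference and 38 to 48 list calls. Of the 115 named calls, 104 passed with quantile normalization, 95 with median scaling, 102 with the replicate block and 60 without the third arrays, and 60 passed whichever single array was left out. Other probe sets of named genes passed in 13 of 41 cases and had the opposite sign in 5: Aldh1a1 from GD13 to GD14 (log2 -0.592) and from GD12 to GD14 (-0.169), C1qb (-0.003) and Cryge (-0.568 and -0.308) from GD12 to GD14, none of which passed themselves.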

Other observations

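The tests of mast cells, osteoclasts and let-7 target genes were chosen only after Cma1, Mmp9 and Hmga2 had been seen among the largest changes.

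Lists of stress response and hypoxia genes had a higher mean on GD14 than on GD12, and neither call held with an estimated correlation. Of 25 immediate early and heat shock genes 4 rose and 0 fell, and 5 rose adjusted over the list alone (mean log2 0.38, camera adjusted p = 0.00325, adjusted p = 0.084 with an estimated correlation). The chaperone gene Hspa1b rose from 45.9 ± 0.755 to 82.5 ± 4.05 (SD, n = 3 each). Ier3 (47.5 ± 10.6 to 102 ± 18.2) and Zfp36 (48.3 ± 9.33 to 101 ± 9.78; SD, n = 3 each) rose as well, with their highest adjusted p at 0.0879 without GD14 replicate 1 and 0.083 without GD14 replicate 2. Klf4, a transcription factor, rose from 174 ± 23.4 to 311 ± 38.6 (SD, n = 3 each), with adjusted p = 0.0532 with the replicate block and 0.134 without GD14 replicate 1. From GD12 to GD13 this list had 1 rise, Egr2 (12.9 ± 5.56 to 56.1 ± 12.8; SD, n = 3 each), and 0 falls, and 3 rises adjusted over the list alone (mean 0.35, camera adjusted p = 0.00154, adjusted p = 0.0761 with an estimated correlation). The adjusted p of Egr2 was 0.0581 with the replicate block and 0.12 without GD13 replicate 2. Of 22 glycolysis and hypoxia response genes 4 rose and 0 fell from GD12 to GD14, and 5 rose adjusted over the list alone (mean 0.27, camera adjusted p = 0.0397, adjusted p = 0.417 with an estimated correlation). Ndrg1, a hypoxia-responsive gene, rose from 109 ± 5.61 to 291 ± 48.0 (SD, n = 3 each), and the collagen prolyl hydroxylase gene P4ha1 from 190 ± 26.8 to 371 ± 45.8, a call that ended without GD14 replicate 1 (adjusted p = 0.0615). P4ha2 rose from 233 ± 31.0 to 416 ± 26.0 (SD, n = 3 each), with adjusted p = 0.0924 without GD12 replicate 2, and Aldoc rose (log2 0.93), with adjusted p = 0.0556 with the replicate block and 0.158 without GD14 replicate 1. The list's adjusted p was 0.0835 with the replicate block, 0.0699 with array weights, 0.235 without the third array of every day, 0.058 without GD12 replicate 1, 0.117 without GD12 replicate 2, 0.0544 without GD13 replicate 3 and 0.276 without GD14 replicate 3. From GD12 to GD13 it had 0 changes among 22 and 2 rises adjusted over the list alone (mean 0.23, camera adjusted p = 0.0286, adjusted p = 0.394 with an estimated correlation). There its adjusted p was 0.0736 with the replicate block, 0.309 without the third array of every day, 0.104 without GD12 replicate 2 and 0.342 without GD13 replicate 3.

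Imprinted and growth factor genes changed in both directions from GD12 to GD14. Dlk1, an imprinted inhibitor of differentiation, rose from 1150 ± 124 to 2590 ± 612 and the IGF carrier Igfbp3 from 334 ± 26.5 to 783 ± 175 (SD, n = 3 each), and Nnat fell. Without GD14 replicate 1 the calls of Dlk1 (adjusted p = 0.0615) and Igfbp3 (0.0569) ended, and another probe set of Igfbp3 did not pass (log2 0.65, adjusted p = 0.558). Of 21 genes in this list 2 rose and 1 fell, also adjusted over the list alone (mean 0.11, camera adjusted p = 0.215), while fry, a test against no change, gave an adjusted p of 0.0191. Of 29 ribosomal protein genes 1 rose, Rpl39l (16.3 ± 2.81 to 61.9 ± 12.0; SD, n = 3 each), and 0 fell, also adjusted over the list alone (mean -0.15, camera adjusted p = 0.0262, adjusted p = 0.627 with an estimated correlation). The ribosomal list's adjusted p was 0.782 with quantile normalization, 0.138 with no filter, 0.0853 with the mean of a gene's probe sets, 0.126 without GD12 replicate 3, 0.101 without GD14 replicate 1 and 0.422 without GD14 replicate 2. It was lower without the third array of every day (0.000267, mean -0.25) and without GD14 replicate 3 (2.26e-05, mean -0.29), and fry, a test against no change, gave 0.445. From GD13 to GD14 the ribosomal list did not pass (mean -0.14, adjusted p = 0.0562), but did with the replicate block (0.0409), without GD13 replicate 2 (0.0221), without GD14 replicate 3 (2.47e-06, mean -0.28) and without the third array of every day (2.49e-05, mean -0.25). Of 70 mitochondrial respiratory chain genes 1 rose, Cox6a2, a muscle form of cytochrome oxidase (12.6 ± 2.49 to 72.0 ± 33.1; SD, n = 3 each), and 0 fell, with 0 adjusted over the list alone. That call ended without GD14 replicate 1 (adjusted p = 0.102). The mitochondrial mean was 0.03 (-0.01 with median scaling), the median -0.03, and the test pointed down (camera adjusted p = 0.661). The marker lists of 4 kinds of cells or tissues did not pass: glia (mean 0.06, camera adjusted p = 0.761, 0 of 10 changed and 2 rises adjusted over the list alone), melanocytes (mean -0.45, adjusted p = 0.106, 1 of 5 fell, Ednrb, from 22.8 ± 4.26 to 7.93 ± 3.53, and 2 adjusted over the list alone), lens and eye (mean 0.56, adjusted p = 0.176, 1 of 9 rose, Cryge, for which 2 of 3 other probe sets had the opposite sign, also adjusted over the list alone), and liver with yolk sac (mean 0.65, adjusted p = 0.215, 1 of 5 rose, also adjusted over the list alone). Without GD12 replicate 1 (adjusted p = 0.0364) or GD14 replicate 2 (0.0237) the melanocyte list passed, and without GD12 replicate 2 (0.0494) or GD14 replicate 3 (0.0429) the lens list did, as it did with array weights (0.0494). Ednrb had its highest adjusted p, 0.111, without GD14 replicate 1.

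Each of 3 hypotheses was tested by camera on marker genes other than the one that raised it, from GD12 to GD14, and by an exact two-sided permutation of the 6 arrays, which cannot go below p = 0.1 and so cannot reach 0.05. Mast cells may account for the rise of Cma1, which rests on 1 probe set. However, the other mast cell genes did not pass (camera p = 0.643, adjusted p = 0.643 over the 3 tests, exact p = 0.3). Of 6 tested, 1 rose, Hdc (12.7 ± 8.97 to 77.7 ± 27.7; SD, n = 3 each), a call that ended without GD12 replicates 1 (adjusted p = 0.0653) or 3 (0.0532) or GD14 replicates 1 (0.0818) or 2 (0.0704). At the same time Cpa3, an abundant mast cell protease, had 14.9 ± 12.1 and 21 ± 6.07 (SD, n = 3 each) and did not pass, so the question stays open. Osteoclasts could account for the rise of Mmp9, since 6 of 8 other osteoclast genes had a positive change. As a list they were higher (camera p = 0.00677, adjusted p = 0.0102, exact p = 0.1), with adjusted p = 0.111 with an estimated correlation and 0.0679 without GD12 replicate 2. Clcn7 (log2 -0.18) and Car2 (-0.16) had a negative change. Of 8 tested, 2 rose, the phosphatase gene Acp5 (26.4 ± 8.49 to 91.4 ± 12.6) and Ctsk (135 ± 8.88 to 430 ± 32.4; SD, n = 3 each), and 2 of the 8 also stood in other lists. Ctsk was among these and had already been called among the matrix proteases. The osteoclast test is thus not independent of results seen before. A fall of let-7 target and oncofetal growth genes could include Hmga2, since all 7 others tested had a negative change (camera p = 0.000441, adjusted p = 0.00132, exact p = 0.1), with adjusted p = 0.111 with an estimated correlation. Of these 7, 1 fell, Mycn (155 ± 20.4 to 92.2 ± 5.81; SD, n = 3 each; adjusted p = 0.0496). That call ended without any one array but GD12 replicate 3, with the highest adjusted p, 0.163, without GD12 replicate 1. Igf2bp1 had 320 ± 152 and 109 ± 20.3 (SD, n = 3 each) without passing. No microRNA was measured, and 2 of the 7 stood in other lists.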
